A study of Mus musculus with 9 samples.

How the data were processed

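Total RNA from frozen medial prefrontal cortex of DBA2/J mice was extracted with a Direct-zol kit, and libraries were made from 1 ug of it with a SureSelect strand-specific kit, per the labels' protocols. The 9 samples fell into 3 groups of 3 by their titles: non-stressed mice (NS), mice given vehicle after 5 days of social defeat (SA:ANH-vehicle), and such mice given an inhibitor of KDM5C (SA:ANH-KDM5Ci). The meaning of SA:ANH was not given in the sources used here. The titles name a vehicle where the treatment labels name saline. Nothing in the labels says that the samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

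The deposited values are expected counts per gene, which need not be whole numbers: among values above 0 and up to 5, 59.6% were whole within 1e-06, and among all values above 0, 15.7% were. Reads were processed with Trimmomatic 0.32, TopHat2 2.0.13 and Bowtie2 2.2.3 against mm10, per the submitters' processing notes. The counting tool and whether it used the strand were not given in the sources used here, so a gene and its antisense partner cannot be told apart in these counts. The table holds 36172 features, of which 16922 were at 0 in all libraries. Features carry NCBI gene IDs; 452 of the IDs have a chromosome suffix. Symbols and positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, and 32891 IDs matched. Of the 19250 features above 0, 19193 matched and 57 did not, and the latter held 0.367% of the counts. 1 unmatched feature held from 0.101% to 0.402% of a library's counts and was highest in NS replicate 1, at 141511 counts. The table of deposited values held 0 columns of other samples.

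Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr, which left 15144, and libraries were scaled by TMM, with factors from 0.987 to 1.01. The test was edgeR's quasi-likelihood test (glmQLFit with robust moderation, edgeR 4.0.16, R 4.3.3), with 1 mean per group in 1 fit of all 9 libraries and Benjamini-Hochberg adjustment over the 15144 genes at 0.05. The standard error of a log2 fold change is its size divided by the square root of its F statistic. CPM values are edgeR's cpm on TMM-scaled library sizes, given as mean and SD of the 3 libraries of a group. The common biological coefficient of variation was 6.95%. Sequencing depth ran from 29845097 to 42196472 counts per library. A count of 0 allows a level of up to 3 counts, which is 0.101 CPM in the shallowest library and 0.0711 CPM in the deepest, and covers counting error only.

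Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists cover immediate early genes, glucocorticoid response, H3K4 methylation enzymes, germline genes, glutamate receptors and transport, GABA receptors and synthesis, monoamine receptors, neuropeptides and receptors, neurotrophin signalling, synaptic vesicle and postsynaptic density, cytokines and NF-kB targets, interferon response, heat shock and unfolded protein response, circadian clock, nuclear oxidative phosphorylation genes, genes of mitochondrial DNA, ribosomal proteins, and markers of excitatory neurons, interneurons, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, endothelium, mural cells, meninges and fibroblasts, choroid plexus and ependyma, blood cells, striatal neurons, and olfactory bulb with thalamus. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 29 lists tested. No member of the mitochondrial DNA list matched a symbol, so that list has no result. Of the other lists' genes, 11 were listed at 0 in all libraries (among them Acta2, Bhlhe41, Lamp5, Myrf and Xbp1), and some of these are active in every brain, so 0 there may be a failed estimate. An estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were alternatives.

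The named genes were chosen per comparison: up to 10 genes per direction with the largest fold change among those that passed the test with groups that did not overlap, at a mean of at least 1 CPM in the higher group and with a symbol of a known gene; up to 5 genes of lowest p in a direction that had fewer; 4 members of lowest p in each called list and at most 2 in each other list; Kdm5a, Kdm5b, Kdm5c and Kdm5d; and Xist and Y genes as a check of sex. Other alternatives were DESeq2 1.42.0 and its size factors, limma-voom, library size without TMM, other filters on low counts, thresholds, only the 2 groups compared, no robust moderation, the replicate number as a block, and each library left out in turn. Scores of striatal and meningeal markers as covariates were added after the data had been seen. A score is the median over a list's members of the gene-centred log2 CPM.

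Tested on simulated counts of 15144 genes, of which 15046 passed the filter, the fit for SA:ANH-KDM5Ci against SA:ANH-vehicle called 80% of 100 genes changed 1.5-fold and 85% of 100 genes changed 2-fold, and 4.69% of all its calls, which include members of a list of 25 genes shifted 1.4-fold, were false. For SA:ANH-KDM5Ci against NS the values were 77%, 86% and 6.77%, and for SA:ANH-vehicle against NS, where no gene was changed, 0 were called. In the same simulated counts the shifted list was called, and 0 of 20 random lists were. Genes were simulated independently, so false calls of lists whose members move together were not tested. Such lists occur here: myelin markers had an estimated correlation of 0.951. The smallest p of an exact permutation test of 3 against 3 samples, two-sided, is 0.1, so single genes were not tested that way. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.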

Results

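Gene expression was measured by RNA sequencing of the medial prefrontal cortex, a frontal region that takes part in the control of emotion and social behaviour, in DBA2/J mice, an inbred strain. Social defeat exposes a mouse repeatedly to an aggressor. Stressed mice of the type that the submitters call SA:ANH received vehicle or an inhibitor of KDM5C, an X-linked H3K4 demethylase, and non-stressed mice (NS) gave the baseline, with 3 samples per group. Total counts per library ran from 29845097 to 36033714 in NS, from 33733470 to 42196472 in SA:ANH-vehicle and from 30525714 to 40700115 in SA:ANH-KDM5Ci. Between 17501 and 17795 genes were above 0 per library, and the 10 most abundant genes held from 2.96% to 3.10% of the counts.

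All 9 libraries had the profile of male tissue. Xist, the RNA of the inactive X chromosome, had 0 to 6 counts, while the Y genes Ddx3y, Uty and Eif2s3y had 2239 to 3537, 581 to 1004 and 953 to 1625 counts. On the first principal component of log2 CPM, with 29.4% of the variance, the SA:ANH-KDM5Ci libraries lay at 21.4, 12.5 and 22.2. The other libraries lay below 0, from -19.3 to -3.39 in NS and from -7.56 to -5.66 in SA:ANH-vehicle. On principal component 2, with 18.5% of the variance, SA:ANH-vehicle replicate 1 lay at -21.6 and SA:ANH-KDM5Ci replicate 1 at -14.7, and on component 3, with 12.4%, NS replicate 1 lay at -19.2. Fos, the activity-induced transcription factor, was at 45.7 CPM there against 8.19 and 8.43 CPM in the other NS libraries.

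SA:ANH-vehicle against NS compares stressed mice of the SA:ANH type given vehicle with non-stressed mice, whose titles name no vehicle. Stress, type and vehicle cannot be told apart in it. Haemoglobin transcripts, which red blood cells carry, were the only genes that passed. Hbb-bs, a beta-globin gene (NCBI gene 100503605, chromosome 7, 103826523 to 103827928, GRCm38), rose from 82.3 ± 5.51 to 143 ± 5.82 CPM (SD, n = 3), a log2 fold change of 0.79 (SE 0.08). Hbb-b1 rose from 45.3 ± 3.10 to 83.6 ± 4.25 CPM, by 0.88 on the log2 scale (SE 0.08). Both had an adjusted p of 0.00143 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Beta-globin copies are near-identical. DBA2/J carries another haplotype of them than the reference strain, so the split of counts between the copies is uncertain. Members of the same list that did not pass were Hba-a2 at 0.73 (adjusted p = 0.0676), Hba-a1 at 0.75 (adjusted p = 0.114) and Alas2, the erythroid enzyme of haem synthesis, at 0.77 (adjusted p = 0.0579).

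Besides the globins, no gene passed in this comparison. The genes of lowest p were Nr1d2 and Dbp, which encode a repressor and an activator of the circadian clock, with log2 fold changes of 0.32 and 0.54, Srsf10, a splicing factor, with 0.32, and Cldn5, the tight junction protein of brain endothelium, with -0.36. All were at an adjusted p of 0.0579 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Usp43 and Chpf2 followed at -0.61 and -0.28 (both adjusted p = 0.0816). Next came Wnt10b, a Wnt ligand, at -1.27 (adjusted p = 0.115). Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, was at 22.8 ± 0.965 CPM in NS and 32.0 ± 1.4 CPM in SA:ANH-vehicle, with a log2 fold change of 0.49 (SE 0.10) and an adjusted p of 0.153. Sgk1, a kinase induced by glucocorticoids, was at 53.0 ± 4.61 and 53.7 ± 2.57 CPM, with a log2 fold change of 0.02 (adjusted p = 0.977), and is given here because of its later change.

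As groups, 8 lists were called higher and 5 lower in SA:ANH-vehicle than in NS by camera with the preset correlation. With an estimated correlation 0 of the 13 calls held. Among 10 blood cell markers, 2 rose over all genes and 5 adjusted over the list alone, with a median log2 fold change of 0.76 (adjusted p = 5.86e-14, and adjusted p = 0.107 with an estimated correlation). By fry the adjusted p of these markers was 0.0237, and no other list was called by fry in this comparison. The heat shock and unfolded protein list had 0 members that passed over all genes and 10 of 21 that rose adjusted over the list alone (median 0.16, adjusted p = 4.97e-12, and adjusted p = 0.351 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, was at 0.31 (adjusted p = 0.139) and Hspb1, a small heat shock protein, at 0.62 (adjusted p = 0.130). Interferon response genes had positive fold changes in 21 of 22, with 0 that passed and 5 that rose adjusted over the list alone (median 0.30, adjusted p = 3.05e-08, and adjusted p = 0.195 with an estimated correlation). Clock genes had 0 of 18 that passed, and 7 rose and 2 fell adjusted over the list alone (median 0.19, adjusted p = 0.000318, and adjusted p = 0.177 with an estimated correlation). Per2, a core clock repressor, was at 21.1 ± 0.847 CPM in NS and 42.1 ± 7.68 CPM in SA:ANH-vehicle, with a log2 fold change of 0.99 (SE 0.18, adjusted p = 0.153).

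The other lists called higher than in NS had no member that passed over all genes. The glucocorticoid response list had a median log2 fold change of 0.12 with 2 of 25 genes that rose adjusted over the list alone (adjusted p = 0.00173, and adjusted p = 0.486 with an estimated correlation). Cytokines and NF-kB targets had a median of 0.19 over 19 genes (adjusted p = 0.00107, and adjusted p = 0.486 with an estimated correlation). Ribosomal proteins had 0.09 over 41 (adjusted p = 3.05e-08, and adjusted p = 0.594 with an estimated correlation) and microglia markers 0.09 over 18 (adjusted p = 0.00334, and adjusted p = 0.594 with an estimated correlation), each with 0 adjusted over the list alone. Lower lists were glutamate receptors and transport (27 genes, median -0.07, adjusted p = 0.00228, and adjusted p = 0.486 with an estimated correlation). The same held for GABA receptors and synthesis (21 genes, median -0.05, adjusted p = 0.0119, and adjusted p = 0.445 with an estimated correlation) and synaptic vesicle and postsynaptic density (35 genes, median -0.04, adjusted p = 0.00412, and adjusted p = 0.445 with an estimated correlation). Astrocyte markers (18 genes, median -0.06, adjusted p = 0.00173, and adjusted p = 0.445 with an estimated correlation) and olfactory bulb with thalamus markers (16 genes, median -0.14, adjusted p = 0.00412, and adjusted p = 0.486 with an estimated correlation) were the remaining lower lists. Adjusted over the list alone, 1 glutamate gene and 2 astrocyte markers fell, and 0 of the GABA, synaptic and olfactory lists did. Medians and means differed in sign for monoamine receptors (-0.03 and 0.03), and the test's direction differed from the median for striatal markers (median -0.02, called neither way). For excitatory neuron markers the median was 0.00 and the test's direction was downward, with no call.

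Over all 15144 genes, 2 rose and 0 fell by edgeR's quasi-likelihood test, against 1244 genes at an unadjusted p under 0.05 where 757 would be expected by chance. DESeq2 called 43 higher and 38 lower and limma-voom 3. Groups did not overlap for 2288 genes, or 15.1%, where chance gives 10%. Without SA:ANH-vehicle replicate 1 or 3 the count was 4, without SA:ANH-KDM5Ci replicate 1 it was 9 and without SA:ANH-KDM5Ci replicate 3 it was 17. The list calls lost without 1 library were glucocorticoid response and cytokines (both adjusted p = 0.0549 without SA:ANH-vehicle replicate 1), synaptic genes (0.0549 without the same library and 0.0837 without NS replicate 2). Others were glutamate (0.0637 without NS replicate 2), GABA (0.0819 and 0.0981 without NS replicate 2 and 3) and olfactory bulb with thalamus (0.116 without NS replicate 3 and 0.0620 without SA:ANH-vehicle replicate 3).

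**Figure D1:**
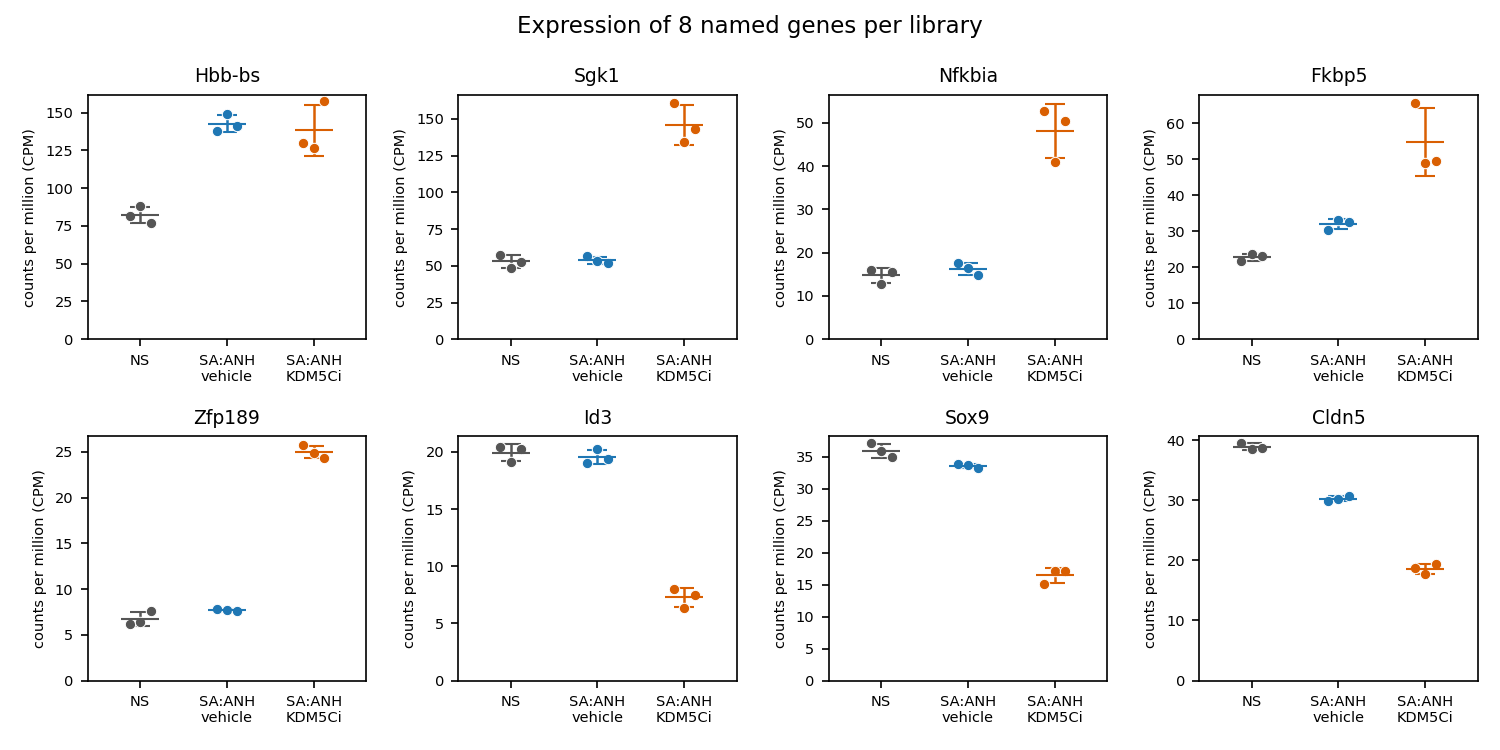
CPM (y axis) of 8 genes in each of the 9 libraries, grouped by NS, SA:ANH-vehicle and SA:ANH-KDM5Ci (x axis), with the group mean and SD. Hbb-bs lies higher in both stressed groups than in NS, Sgk1, Nfkbia, Fkbp5 and Zfp189 lie higher in SA:ANH-KDM5Ci, and Id3, Sox9 and Cldn5 lie lower there.

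SA:ANH-KDM5Ci against SA:ANH-vehicle asks what the inhibitor changed in stressed mice. More glucocorticoid response genes rose than members of any other list, and the largest decreases include Id3 and Hes5, regulators of neural stem cells. Sgk1 (gene 20393, chromosome 10, 21882184 to 21999903) rose from 53.7 ± 2.57 to 146 ± 13.5 CPM (SD, n = 3), 2.71-fold, with a log2 fold change of 1.44 (SE 0.08). Zfp189, a zinc finger transcription factor (gene 230162, chromosome 4, 49521176 to 49531558), rose 3.24-fold from 7.71 ± 0.0818 to 25 ± 0.704 CPM. Id3, an inhibitor of basic helix-loop-helix factors (gene 15903, chromosome 4, 136143822 to 136145392), fell by 1.42 on the log2 scale (SE 0.08), from 19.5 ± 0.616 to 7.28 ± 0.856 CPM. Their adjusted p values were 5.96e-07, 3.22e-07 and 1.2e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all 3 calls held in each of the 9 fits that left out 1 library.

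Of 25 glucocorticoid response genes, 13 rose and 0 fell over all genes, and 16 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 0.54. Besides Sgk1, members of low p were Nfkbia, the inhibitor of NF-kB, which rose from 16.3 ± 1.35 to 48.1 ± 6.26 CPM (log2 1.56, SE 0.11). Ddit4, a stress-induced inhibitor of mTORC1, rose from 24.6 ± 1.91 to 62.6 ± 10.8 CPM (log2 1.34, SE 0.11), and Errfi1, a feedback inhibitor of EGF receptor signalling, by 0.62. The adjusted p values of Nfkbia, Ddit4 and Errfi1 were 1.01e-05, 9.01e-05 and 5.78e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Map3k6, a stress-activated kinase, rose by 1.77 (adjusted p = 0.000188). Fkbp5 rose from 32.0 ± 1.4 to 54.7 ± 9.46 CPM (log2 0.77, adjusted p = 0.00113) and Tsc22d3, the glucocorticoid-induced leucine zipper protein, by 0.71 (adjusted p = 0.000381), a pair chosen after their values were seen. As a list these genes were called higher by camera (adjusted p = 3.27e-24, and adjusted p = 0.156 with an estimated correlation), with a range over all alternatives from 3.29e-27 to 0.156. By fry the list's adjusted p was 0.00561. With the striatal and the meningeal score as a covariate 10 and 7 of the 13 calls were kept.

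Among the other genes with the largest rise were Tmem252, which went from 0.599 ± 0.294 to 6.88 ± 2.81 CPM, 11.1-fold (log2 3.47, SE 0.34), and Maff, a small Maf transcription factor, from 1.01 ± 0.0971 to 5.40 ± 0.713 CPM, 5.36-fold (adjusted p = 9.61e-06). Pmaip1, a pro-apoptotic BCL2 family member, rose by 1.69 on the log2 scale, Rasd1, a Ras protein first found as induced by dexamethasone, by 1.61, Fam83d by 2.09, and Ada, adenosine deaminase, by 1.84. Plin4, a lipid droplet protein of the glucocorticoid list, rose by 1.76 (adjusted p = 0.0215) and Wnt3, a Wnt ligand, by 1.58 (adjusted p = 0.0233), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call of Ada was lost without SA:ANH-vehicle replicate 2 (adjusted p = 0.0578), that of Plin4 without SA:ANH-vehicle replicate 2 or 3 (0.0977 and 0.0756), and that of Wnt3 without any 1 of the 6 libraries compared (up to 0.111). With the meningeal score as a covariate, which was added after the data had been seen, the calls of Tmem252, Fam83d, Ada, Plin4 and Wnt3 were lost (adjusted p = 0.0663, 0.0546, 0.185, 0.146 and 0.535), at log2 fold changes of 3.69, 1.79, 2.14, 2.36 and 0.98.

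Among the 10 largest decreases, Tnfsf10, a death ligand induced by interferon, fell by 1.63 on the log2 scale (adjusted p = 0.00078), Ptgdr, a prostaglandin D2 receptor, by 2.10 (adjusted p = 0.00634) and Gbp4, an interferon-induced GTPase, by 1.44 (adjusted p = 0.00263). Tgtp1 and Tgtp2, interferon-induced GTPases, fell by 1.63 and 1.54, though these are near-identical copies whose counts may be split between them. Hes5, a Notch-induced repressor of neural stem cells (gene 15208, chromosome 4, 154960626 to 154962372), fell by 1.59 (SE 0.20), from 13 ± 1.86 to 4.37 ± 1.47 CPM (adjusted p = 0.00259). Each of these 6 calls, made by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, held when any 1 library was left out. Calls that depended on single libraries were Cyp2a5, which fell by 2.80 and lost its call without any of 7 libraries (adjusted p up to 0.167), and Foxc2, a forkhead factor of mesenchyme, which fell by 1.45 and lost it without any of 4 (up to 0.0921). Hcar1, a lactate receptor, fell by 1.36 and lost its call without SA:ANH-vehicle replicate 1 (0.0601) or SA:ANH-KDM5Ci replicate 2 (0.0597). With the meningeal score as a covariate the calls of Ptgdr, Gbp4, Tgtp1 and Tgtp2 were lost (adjusted p = 0.247, 0.129, 0.095 and 0.146) at log2 fold changes of -1.46, -1.15, -1.64 and -1.35. Those of Cyp2a5, Foxc2 and Hcar1 were lost as well (adjusted p = 0.441, 0.484 and 0.482), at -2.51, -0.87 and -0.75.

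Of 22 interferon response genes, 0 rose and 4 fell over all genes, and 11 fell adjusted over the list alone (median -0.52, adjusted p = 3.82e-08 by camera, and adjusted p = 0.294 with an estimated correlation). By fry the adjusted p of this list was 0.0389. Irf9, a subunit of the interferon-activated transcription factor, fell from 9.92 ± 0.422 to 6.80 ± 0.218 CPM (log2 -0.54, SE 0.09, adjusted p = 0.00551) and Oasl2, an antiviral protein, fell by 0.98 (adjusted p = 0.00716) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ifit3 and Isg15, also antiviral, fell by 0.50 and 1.02 (adjusted p = 0.0414 and 0.0441), calls that were lost without any of 6 and 8 of the 9 libraries, with adjusted p up to 0.190 without SA:ANH-vehicle replicate 2. With the meningeal score as a covariate all 4 calls were lost, with Irf9 at -0.64 (adjusted p = 0.0517), Oasl2 at -0.67 (0.345), Ifit3 at -0.44 (0.45) and Isg15 at -1.14 (0.28). Relative to NS, Irf9 was at -0.17 (adjusted p = 0.355).

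Vessel genes moved both ways. Of 18 endothelial markers, 1 rose and 3 fell over all genes, and 1 rose and 4 fell adjusted over the list alone (median -0.16, adjusted p = 0.000905 by camera, and adjusted p = 0.770 with an estimated correlation). Cldn5 (gene 12741, chromosome 16, 18776847 to 18778262) fell from 30.3 ± 0.410 to 18.6 ± 0.842 CPM (log2 -0.70, SE 0.06) and Kdr, a VEGF receptor, from 16.6 ± 2 to 9.32 ± 0.873 CPM (-0.84, SE 0.10), while Slco1a4, an organic anion transporter, fell by 0.43, a call lost with the meningeal score as a covariate (log2 -0.36, adjusted p = 0.290). Slc2a1, the glucose transporter of the blood-brain barrier (gene 20525, chromosome 4, 119108745 to 119137330), rose from 81.0 ± 3.22 to 149 ± 13.8 CPM (log2 0.88, SE 0.07). The adjusted p values of the 4 genes were 1.56e-05, 0.00036, 0.00882 and 1.33e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mural cell markers had 0 of 13 that rose and 2 that fell, and 3 fell adjusted over the list alone (adjusted p = 0.175 by camera). Pdgfrb, the PDGF receptor of pericytes, fell by 0.45 (adjusted p = 0.00858, and log2 -0.32 with 0.361 with the meningeal score as a covariate). Anpep, a peptidase, fell by 0.74 (adjusted p = 0.0492), a call lost without any of 7 libraries (up to 0.172) and with that covariate (log2 -0.21, adjusted p = 0.802).

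Sox9, a transcription factor of astrocytes and neural stem cells (gene 20682, chromosome 11, 112782210 to 112787757), fell from 33.6 ± 0.287 to 16.4 ± 1.14 CPM (log2 -1.03, SE 0.06, adjusted p = 1.2e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and was the 1 astrocyte marker of 18 that passed. Adjusted over the list alone 1 rose and 1 fell. In the oligodendrocyte precursor list 3 of 14 rose and 0 fell, and 4 rose and 2 fell adjusted over the list alone (median 0.15, adjusted p = 0.0431 by camera, and adjusted p = 0.770 with an estimated correlation). Olig2 and Olig1, transcription factors of the oligodendrocyte lineage, rose by 0.72 (adjusted p = 0.0196) and 0.47 (adjusted p = 0.0416), and Vcan, a matrix proteoglycan, by 0.34 (adjusted p = 0.0326). These calls were lost without any of 4, 7 and 4 libraries (adjusted p up to 0.112, 0.191 and 0.148). P2ry13, a purinergic receptor of microglia, fell by 0.79 (adjusted p = 0.000822), the 1 microglia marker of 18 that passed over all genes or over the list alone. In both the astrocyte list (median 0.04, mean -0.00) and the microglia list (median 0.06) camera's direction was up and fry's down, and neither was called.

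Receptor genes of neurons showed single changes within groups that were not called. Cckbr, the brain cholecystokinin receptor, fell from 79.8 ± 6.88 to 52.7 ± 2.78 CPM (log2 -0.60, SE 0.06, adjusted p = 0.000209) and Npy1r, a neuropeptide Y receptor, by 0.60 (adjusted p = 0.00036) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were the 2 of 26 neuropeptide genes that fell, with 3 adjusted over the list alone and 0 that rose. That list's median was 0.06 where fry's direction was down. Grm2, a presynaptic glutamate receptor, was the 1 of 27 glutamate genes that passed and fell by 0.37 (adjusted p = 0.0282), and Adrb1, a beta-adrenergic receptor, the 1 of 23 monoamine receptors, by 0.45 (adjusted p = 0.0307). These calls were lost without any of 5 and 6 libraries (up to 0.132 and 0.151). GABA genes (21), synaptic genes (35) and interneuron markers (17) had 0 that passed over all genes or over the list alone, and excitatory neuron markers 0 of 16 and 1 that rose adjusted over the list alone. For these 0 counts, 0, 1, 1 and 8 genes had an unadjusted p under 0.05. Vegfa, the vascular growth factor, was the 1 of 18 neurotrophin signalling genes that passed and fell by 0.31 (adjusted p = 0.0112), a call lost without SA:ANH-vehicle replicate 2 (0.0709) or SA:ANH-KDM5Ci replicate 1 (0.0509).

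Among 30 immediate early genes, 3 rose and 0 fell over all genes and over the list alone (median 0.05, adjusted p = 0.00419 by camera, and adjusted p = 0.770 with an estimated correlation). They were Maff, Apold1, a vascular early response gene, which rose by 1.52 (SE 0.15, adjusted p = 0.000122), and Dusp5, a MAP kinase phosphatase, which rose by 1.07 (adjusted p = 0.0104, and log2 0.92 with 0.348 with the meningeal score as a covariate), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Fos had 29.7, 10.8 and 15.1 CPM in SA:ANH-vehicle and 14.3, 18.5 and 12.6 CPM in SA:ANH-KDM5Ci. Cytokines and NF-kB targets had 1 of 19 that rose, Nfkbia, and 1 that fell, Cxcl12, a chemokine of vessels and meninges, by 0.61 (adjusted p = 0.00444, and log2 -0.47 with 0.21 with the meningeal score as a covariate). In the heat shock and unfolded protein list 1 of 21 rose, Atf4, the effector of the integrated stress response, by 0.34 (adjusted p = 0.0303), lost without any of 6 libraries (up to 0.137). Clock genes had 0 of 18 that passed, with 2 that rose and 3 that fell adjusted over the list alone. None of these last 3 lists was called, and the cytokine and heat shock counts were the same adjusted over the list alone.

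Meningeal and fibroblast markers had 0 of 16 that rose and 2 that fell over all genes, and 14 fell adjusted over the list alone (median -0.67, adjusted p = 2.07e-11 by camera, and adjusted p = 0.770 with an estimated correlation). Slc22a6, an anion transporter of the meninges, fell by 0.96 (adjusted p = 0.0212) and Lum, a collagen-binding proteoglycan, by 1.04 (adjusted p = 0.0329) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Their calls were lost without any of 3 and 5 libraries (up to 0.109 and 0.115). The meningeal score was 0.67, 0.05 and -0.02 in SA:ANH-vehicle and -0.51, -0.38 and -0.33 in SA:ANH-KDM5Ci. Striatal neuron markers had 0 of 16 that passed, 7 at an unadjusted p under 0.05 and 16 positive fold changes (median 0.93, adjusted p = 5.12e-08 by camera, and adjusted p = 0.770 with an estimated correlation). Their scores were 0.05, -0.31 and -0.47 in SA:ANH-vehicle and 1.26, -0.14 and 0.57 in SA:ANH-KDM5Ci. Oligodendrocyte and myelin markers had 0 of 18 that passed (0 at an unadjusted p under 0.05, median 0.38, adjusted p = 6.15e-05 by camera, and adjusted p = 0.770 with an estimated correlation). Nuclear oxidative phosphorylation genes (0 of 35, median 0.08) and ribosomal proteins (0 of 41, median 0.07) were called higher, both at an adjusted p of 0.000149 by camera and adjusted p = 0.770 with an estimated correlation.

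The remaining lists were not called. Choroid plexus and ependymal markers had 0 of 9 that passed, blood cell markers 0 of 10, and germline genes 0 of the 9 of 30 that could be tested. Olfactory bulb with thalamus markers had 1 of 16 that fell, or 2 adjusted over the list alone: Lef1, a Wnt-pathway factor, by 0.63 (adjusted p = 0.0358 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lost without any of 5 libraries, up to 0.148). Of 24 H3K4 methylation enzymes 0 rose and 1 fell, Kdm1b, a flavin-dependent H3K4 demethylase, by 0.37 (adjusted p = 0.0365), lost without any of 8 libraries (up to 0.154). Kdm5c itself (gene 20591, chromosome X, 152233198 to 152279102) was at 62.1 ± 0.77 CPM in NS, 63.8 ± 2.9 CPM in SA:ANH-vehicle and 58.3 ± 1.0 CPM in SA:ANH-KDM5Ci. Kdm5a, Kdm5b, Kdm5c and Kdm5d had log2 fold changes of -0.06, -0.10, -0.13 and -0.10 between the stressed groups (adjusted p = 0.716, 0.582, 0.222 and 0.762), of 0.02, -0.03, 0.04 and -0.02 for SA:ANH-vehicle against NS (0.969, 0.959, 0.900 and 0.988) and of -0.04, -0.13, -0.09 and -0.12 for SA:ANH-KDM5Ci against NS. None of the 4 passed in any comparison. An inhibitor of the enzyme need not change its transcript, so these levels do not measure the inhibition.

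Over all genes, 135 rose and 245 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 2150 genes at an unadjusted p under 0.05. Of these, 58 rose and 99 fell at least 1.5-fold, and the median size of the 380 changes was 0.52 on the log2 scale. Groups did not overlap for 2856 genes, or 18.9%, where chance gives 10%. With the striatal score as a covariate 47 rose and 68 fell, and with the meningeal score 34 rose and 33 fell. The count was 253 without SA:ANH-vehicle replicate 1, 203 without SA:ANH-vehicle replicate 2, 204 without SA:ANH-KDM5Ci replicate 3 and 593 at an adjusted p under 0.10. Of 52 named genes that were called, 24 lost the call with the striatal score and 32 with the meningeal score, all in the same direction, and every gene whose call was lost without a library is among both. Their fold changes on the log2 scale were a median of 0.922 times (from 0.57 to 1.25) and 0.85 times (from 0.285 to 1.34) those without the covariate, and their median SE went from 0.175 to 0.231 and from 0.187 to 0.215. Ptgdr, Oasl2, Slco1a4 and Dusp5 lost the call with the striatal score at -1.84, -1.04, -0.42 and 0.96 (adjusted p = 0.0932, 0.0647, 0.0938 and 0.118). List calls lost without 1 library were immediate early genes (adjusted p = 0.0855 without SA:ANH-vehicle replicate 2), oxidative phosphorylation (0.632 without SA:ANH-KDM5Ci replicate 3), ribosomal proteins (0.160 without SA:ANH-vehicle replicate 1 and 0.337 without SA:ANH-KDM5Ci replicate 3) and oligodendrocyte precursor markers (0.0511 and 0.153 without SA:ANH-vehicle replicate 2 and 3, 0.178 without SA:ANH-KDM5Ci replicate 1 and 0.0502 with DESeq2 size factors).

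**Figure D2:**
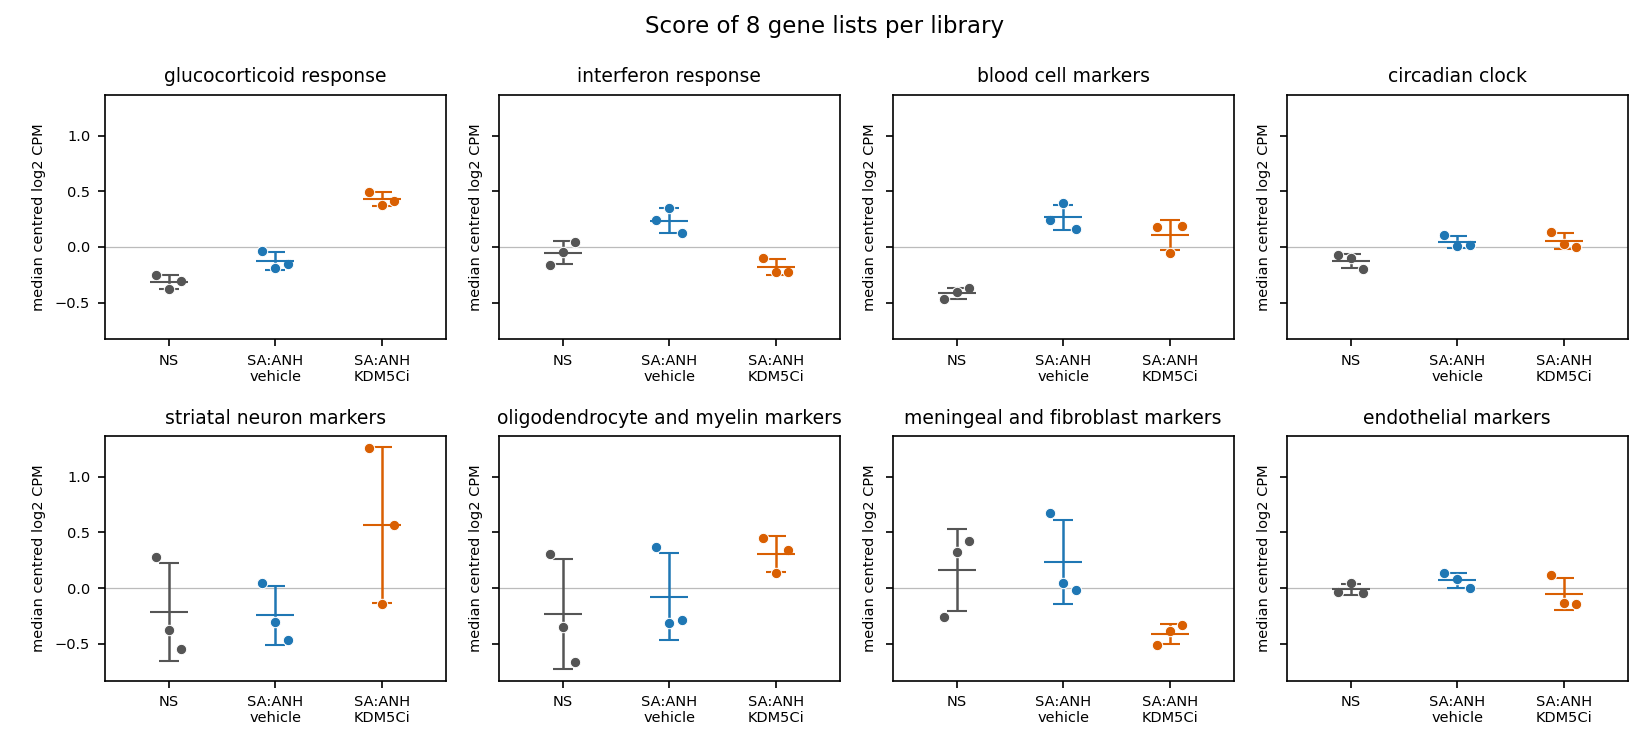
Score of 8 gene lists (y axis, the median over members of the gene-centred log2 CPM) in each of the 9 libraries, grouped by NS, SA:ANH-vehicle and SA:ANH-KDM5Ci (x axis). The glucocorticoid scores lie highest in SA:ANH-KDM5Ci, with group means of -0.31, -0.13 and 0.43, and the interferon scores highest in SA:ANH-vehicle, with -0.05, 0.24 and -0.18.

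SA:ANH-KDM5Ci against NS asks how stressed mice given the inhibitor differ from non-stressed ones. Among the 10 genes with the largest rise were Tmem252 (18.6-fold), Maff (7.93-fold), Fam83d (7.54-fold) and Zfp189 (3.73-fold). So were Fas, a death receptor, which rose 4.74-fold (log2 2.25, SE 0.22), Mc4r, a melanocortin receptor, by 2.15 on the log2 scale (1.68 with adjusted p = 0.0548 with the meningeal score as a covariate), and Cebpd, a transcription factor of inflammation, by 2.05. Their adjusted p values were 0.000128, 1.46e-06, 2.22e-05, 1.02e-07, 7.46e-05, 0.00125 and 0.000256 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cldn5 fell from 39.0 ± 0.541 to 18.6 ± 0.842 CPM (log2 -1.06, adjusted p = 3.46e-07), and Hes5 fell by 1.66, Id3 fell by 1.45 and Sox9 fell by 1.13 on the log2 scale. Mycn, a proto-oncogene of neural progenitors, fell by 1.30, and Tbx3 and Hhex, developmental transcription factors, by 1.23 and 1.2.

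Of 25 glucocorticoid response genes, 15 rose and 0 fell over all genes, and 20 rose and 1 fell adjusted over the list alone (median 0.65, adjusted p = 4.3e-25 by camera, and adjusted p = 0.143 with an estimated correlation). Fkbp5 rose 2.39-fold, from 22.8 ± 0.965 to 54.7 ± 9.46 CPM (adjusted p = 2.25e-05), and Tsc22d3 2.03-fold (adjusted p = 2.02e-05), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Blood cell markers had 5 of 10 that rose and 6 adjusted over the list alone (median 0.67, adjusted p = 3.94e-06 by camera, and adjusted p = 0.286 with an estimated correlation). Hbb-bs rose by 0.75 and Hbb-b1 by 0.81 (both adjusted p = 0.000149), with Hba-a1, Hba-a2 and Alas2 at 0.69, 0.69 and 0.65 (0.0160, 0.00678 and 0.01, the last lost without NS replicate 3 at 0.0541, and Hba-a2 with the meningeal score as a covariate at log2 0.59 and 0.149). Heat shock and unfolded protein genes had 3 of 21 that rose, Hspa5, Hspb1 and Hsp90b1, and 9 adjusted over the list alone (median 0.16, adjusted p = 1.34e-07 by camera, and adjusted p = 0.702 with an estimated correlation). Their calls were lost without any of 1, 4 and 6 libraries (adjusted p up to 0.0627, 0.0985 and 0.109). Among 18 clock genes Nr1d2 rose by 0.26 (adjusted p = 0.00992, lost without either of 2 libraries, up to 0.0512) and Nr1d1, its paralog, fell by 0.39 (adjusted p = 0.00349, and log2 -0.32 with 0.0847 with the meningeal score as a covariate). Adjusted over the list alone 8 rose and 2 fell (median 0.19, adjusted p = 0.00214 by camera, and adjusted p = 0.286 with an estimated correlation).

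Neuronal receptors that fell against NS included Grm2, from 104 to 63.1 CPM on average (log2 -0.73, adjusted p = 0.000189), Cckbr (adjusted p = 0.000161), Npy1r and Adrb1, all held when any 1 library was left out. Interferon response genes were not called (median -0.11), with 1 of 22 that rose and 1 that fell, and 2 and 1 adjusted over the list alone. Endothelial markers were not called either, with 1 of 18 that rose, Slc2a1 at 2.18-fold (adjusted p = 1e-06), and 4 that fell. The striatal, myelin and meningeal lists were called in both comparisons with SA:ANH-KDM5Ci, which share its libraries. Striatal markers had a median of 0.86 (0 of 16 passed, adjusted p = 5.72e-07 by camera, and adjusted p = 0.702 with an estimated correlation), myelin markers 0.53 (0 of 18, adjusted p = 8.07e-07, and adjusted p = 0.702 with an estimated correlation). Meningeal markers had a median of -0.62 (1 of 16 fell and 7 adjusted over the list alone, adjusted p = 3.57e-08, and adjusted p = 0.702 with an estimated correlation). Olfactory bulb with thalamus markers, not called between the stressed groups, had -0.46 (2 of 16 fell and 3 adjusted over the list alone, adjusted p = 0.00247, and adjusted p = 0.702 with an estimated correlation). Ribosomal proteins (41, median 0.16, 0 over all genes and 5 that rose adjusted over the list alone, adjusted p = 3.72e-13) and nuclear oxidative phosphorylation genes (35, median 0.08, adjusted p = 0.000657) were called higher, with adjusted p = 0.702 with an estimated correlation for both. Also called were microglia markers (median 0.17, 1 of 18 fell, and 6 rose and 2 fell adjusted over the list alone, adjusted p = 0.0303, and adjusted p = 0.702 with an estimated correlation). So were immediate early genes (median 0.02, 3 of 30 rose and 1 fell over all genes and over the list alone, adjusted p = 0.0411, and adjusted p = 0.742 with an estimated correlation) and H3K4 methylation enzymes (median -0.08, 1 of 24 fell and 2 adjusted over the list alone, adjusted p = 0.0411, and adjusted p = 0.702 with an estimated correlation). Medians and tests differed in sign for mural markers (median 0.02, mean -0.04) and excitatory neuron markers (median -0.00, mean 0.03), which were not called.

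Over all genes, 281 rose and 320 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 2796 at an unadjusted p under 0.05. Groups did not overlap for 3555 genes, or 23.5%, where chance gives 10%. Both comparisons with SA:ANH-KDM5Ci shared 113 genes that rose, where independent lists would share 2.50, and 148 that fell, where they would share 5.18, and 0 genes were called in opposite directions. The SA:ANH-KDM5Ci libraries are in both comparisons and 3 of them cannot be split, so the values for independent lists are no baseline here. How much of the excess comes from the shared libraries was not tested. The count was 152 with the striatal score and 159 with the meningeal score as a covariate. Of 59 named genes that were called, 26 lost the call with the striatal and 29 with the meningeal score, all in the same direction, with a median fold change on the log2 scale of 0.961 and 0.868 times that without the covariate and a median SE from 0.107 to 0.134 and from 0.111 to 0.155. The count was 318 without NS replicate 2, 269 without NS replicate 3, 279 without SA:ANH-KDM5Ci replicate 1, 398 without SA:ANH-KDM5Ci replicate 3 and 1017 at an adjusted p under 0.10. List calls lost without 1 library were immediate early genes (adjusted p = 0.679, 0.763 and 0.175 without NS replicate 2, NS replicate 3 and SA:ANH-KDM5Ci replicate 2, but 6.07e-12 without NS replicate 1, the library with high Fos) and H3K4 enzymes (0.149 and 0.274 without NS replicate 2 and SA:ANH-KDM5Ci replicate 3). Others were oxidative phosphorylation (0.604 without SA:ANH-KDM5Ci replicate 3) and microglia markers (0.0786 and 0.573 without NS replicate 1 and SA:ANH-KDM5Ci replicate 1).

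Whether genes that differed between SA:ANH-vehicle and NS moved back with the inhibitor was examined across all genes. Hbb-bs and Hbb-b1, the genes that rose in SA:ANH-vehicle against NS, were at -0.05 and -0.08 between the stressed groups and did not pass. No gene was called in both comparisons over all genes. At an unadjusted p under 0.05, 213 genes moved in opposite directions and 74 in the same one, with 153 up and then down where independent lists would give 55.7. Pearson's r across the 15144 genes, which are not independent replicates, was -0.27. The SA:ANH-vehicle libraries enter both fold changes with opposite signs. In 100 simulations with no effect the mean r was -0.487 and 95% of them lay from -0.513 to -0.461. The covariance was -0.0123 where the simulations gave -0.0131 (95% from -0.0142 to -0.0121), a difference of 0.000782. With all libraries, opposite movement was thus no larger than in the simulations. Leaving out a library turned the sign of the covariance difference, to -0.00153, -0.0035, -0.00465 and -0.00589 without NS replicate 2, NS replicate 3, SA:ANH-vehicle replicate 3 and SA:ANH-KDM5Ci replicate 1. The simulations drew genes independently, so their range leaves out genes that move together. Whether opposite movement exceeds what the shared libraries alone give remains open.

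**Figure D3:**
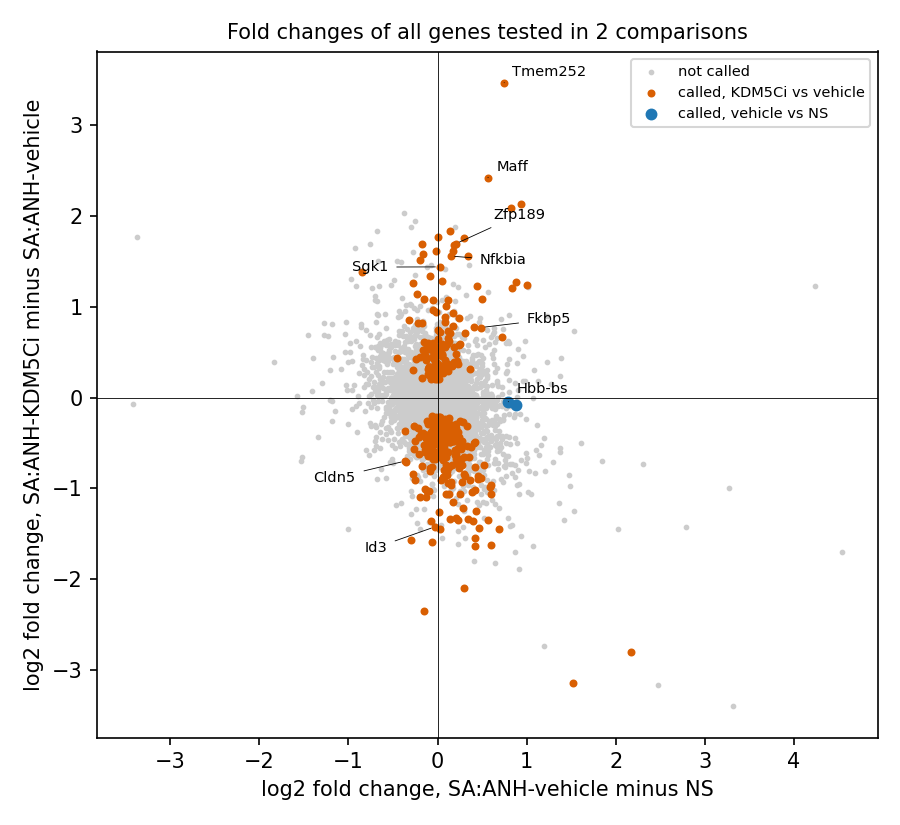
Log2 fold change of SA:ANH-KDM5Ci minus SA:ANH-vehicle (y axis) against that of SA:ANH-vehicle minus NS (x axis), with 1 point per gene tested and colours for genes called in either comparison. The 380 genes called with the inhibitor lie mostly near 0 on the x axis, and the 2 called in SA:ANH-vehicle against NS lie near 0 on the y axis.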

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

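The striatal and meningeal covariates were chosen after the data had been seen; the other alternatives were fixed beforehand. Genes changed in SA:ANH-vehicle against NS numbered 2, and 176 at an unadjusted p under 0.05 with 1.5-fold, 15 at an adjusted p under 0.10, 11 with library size only, 11 with no filter on low counts, 81 by DESeq2, 17 with only the 2 groups compared, 6 with the meningeal covariate and 2 to 17 when a library was left out (4 without SA:ANH-vehicle replicate 1 or 3, 9 without SA:ANH-KDM5Ci replicate 1, 17 without SA:ANH-KDM5Ci replicate 3). For SA:ANH-KDM5Ci against SA:ANH-vehicle the 380 became 593 at an adjusted p under 0.10, 115 with the striatal covariate (106 of them among the 380), 67 with the meningeal one (64 of them) and 203 to 429 when a library was left out (253, 203 and 204 without SA:ANH-vehicle replicate 1, SA:ANH-vehicle replicate 2 and SA:ANH-KDM5Ci replicate 3). For SA:ANH-KDM5Ci against NS the 601 became 1017, 152 and 159 under the same settings and 269 to 747 when a library was left out (318, 269, 279 and 398 without NS replicate 2, NS replicate 3, SA:ANH-KDM5Ci replicate 1 and SA:ANH-KDM5Ci replicate 3). All other alternatives stayed within 1.5 times these counts. Looser thresholds call more by construction. A fit with fewer libraries or with a covariate has fewer degrees of freedom, which by itself favours fewer calls and does not account for counts that rose. In SA:ANH-vehicle against NS the count was 17 with only the 2 groups compared. It was 9, 2 and 17 without SA:ANH-KDM5Ci replicate 1, 2 and 3. The 2 calls of that comparison thus depended on SA:ANH-KDM5Ci libraries, which share its fit. Beyond that the cause was not tested.

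Lists called numbered 13, 10 and 13 in the 3 comparisons, 0, 0 and 0 with an estimated correlation, 1, 2 and 3 by fry, and 12 to 17, 8 to 13 and 11 to 14 when a library was left out. Those called by fry were blood cell markers in SA:ANH-vehicle against NS, and glucocorticoid and interferon response between the stressed groups. In SA:ANH-KDM5Ci against NS they were glucocorticoid response, blood cell markers and clock genes. Of 36 list calls, 29 had their highest adjusted p with an estimated correlation, and the lowest adjusted p over a list's alternatives ran from 3.29e-27 to 0.00976. The estimated correlation is high where members rise and fall together between libraries, and the cause was not tested further.

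The difference between observed and simulated covariance was 0.000782 as reported, 0.00287 with genes of a mean of at least 5 CPM and -0.00589 to 0.00481 when a library was left out, negative (-0.00153, -0.0035, -0.00465 and -0.00589) without NS replicate 2, NS replicate 3, SA:ANH-vehicle replicate 3 and SA:ANH-KDM5Ci replicate 1; the cause was not tested. Of named genes that were called, the alternatives other than leaving out a library kept the call in 1089 of 1242 fits and lost it in 153, leaving out a library kept it in 819 of 1017 and lost it in 198, and 0 reversed. Of 400 fits of genes not called, 33 passed the threshold and 10 reversed, all in the Kdm5 family near 0. With the meningeal covariate Kdm5a was at 0.0956 and Kdm5d at 0.0103 between the stressed groups and Kdm5a at 0.0993 in SA:ANH-KDM5Ci against NS. Leaving out a library gave Kdm5a -0.036 to 0.0577, Kdm5b -0.0563 to 0.0125 and Kdm5d -0.0977 to 0.0659 in SA:ANH-vehicle against NS, and Kdm5d -0.185 to 0.0313 between the stressed groups and -0.203 to 0.0129 in SA:ANH-KDM5Ci against NS.

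Replicate numbers did not pair the samples across all 3 groups. Same-numbered libraries had deviations correlated from -0.144 to 0.238, above 0.1 in 3 of 9 pairs, and 4 of 9 libraries correlated best with their own number. Between SA:ANH-vehicle and SA:ANH-KDM5Ci the same-numbered pairs were at 0.238, 0.0839 and 0.184, and pairs of unlike number ran from -0.251 to 0.0851. A pairing of these 2 groups thus remains open. With the replicate block, 2, 363 and 708 genes and 14, 10 and 12 lists were called. A block leaves the group differences of a balanced design unchanged on the log2 scale, so the covariance difference stayed at 0.000782 and is no check of pairing. The block ended the call of the immediate early genes in SA:ANH-KDM5Ci against NS (adjusted p = 0.0663), and the cause was not tested. Libraries held 29845097 counts or more, and whether depth or the spread between 3 samples is the limit for most genes was not tested.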

Other observations

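All tests of explanations were chosen after the fold changes had been seen, except the splits of the libraries of each comparison. A list of sterol genes was drawn up after some of its members had been seen low, so its p is no independent test. Of 24 sterol genes, 0 passed in SA:ANH-vehicle against NS by edgeR's quasi-likelihood test, with 21 lower at an unadjusted p under 0.05 and 23 negative fold changes (median -0.27, camera p = 0.01302 with an estimated correlation). In SA:ANH-KDM5Ci against NS 17 fell (median -0.38, camera p = 0.0211 with an estimated correlation). Between the stressed groups 1 of 24 fell, with 21 negative fold changes (median -0.09, camera p = 0.307 with an estimated correlation). Idi1, which makes isoprenoid units, was at 71.8, 59.6 and 47.9 CPM in NS, SA:ANH-vehicle and SA:ANH-KDM5Ci. Insig1, the sterol-regulated retention protein, was at 108, 85.6 and 76.3 CPM.

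Id3, Hes5 and Sox9 had company among 20 targets of Notch and BMP signalling: 8 fell and 0 rose between the stressed groups (median -0.21, camera p = 0.001316 with an estimated correlation), and 9 fell against NS (median -0.23, p = 0.00122 in the same way). Id1, Hey2, Heyl and Nrarp fell by 0.59, 0.58, 0.75 and 0.52 on the log2 scale. That list was drawn up after these genes had been seen, so its p is no independent test. A lower activity of Notch or BMP signalling may lie behind the group and was not tested apart from that. Markers of astrocytes, which express Sox9, had a median of 0.04 between the stressed groups, with 13 of 18 positive. Endothelial markers had a median of -0.16 with 15 of 18 negative, and mural markers -0.07 with 9 of 13 negative. Meningeal and fibroblast markers had -0.67 with 16 of 16 negative. With the striatal and the meningeal score as a covariate, Id3 was at -1.54 and -1.48 between the stressed groups, and Hes5 at -1.65 and -1.79. Both calls held by edgeR's quasi-likelihood test (adjusted p = 2.84e-05 and 7.99e-05 for Id3, and 0.0263 and 0.0361 for Hes5). These 2 genes were picked for their fall, so they do not speak for the other members. Whether the makeup of the tissue plays a part in the fall of the group as a whole was not tested.

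In SA:ANH-vehicle against NS, 0 of 17 heat-induced genes passed by edgeR's quasi-likelihood test, with 8 at an unadjusted p under 0.05 and 16 positive fold changes (median 0.12, camera p = 0.0133 with an estimated correlation). That list was drawn up after Srsf10, Tra2a and Chordc1 had been seen high, and without Cirbp and Rbm3, so its p is no independent test. In SA:ANH-KDM5Ci against NS 14 of the 17 were positive (camera p = 0.101 with an estimated correlation). Srsf10, Tra2a and Chordc1 were at 0.32, 0.33 and 0.28, and the cold-induced Cirbp and Rbm3 at -0.30 and -0.26. Whether body temperature at sampling differed remains open, since the labels do not record it.

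Glucocorticoid response genes were higher in SA:ANH-KDM5Ci than in SA:ANH-vehicle. In libraries thinned to 29844993 counts all 13 calls were kept, so the calls did not rest on unequal depth. The median log2 fold change over the 25 genes was 0.5662 there (jackknife SE 0.145) against 0.54. Random thinning keeps each gene's expected share of its library, so this median could hardly move and is no test of depth as a cause. With the striatal and the meningeal score as a covariate the median fell to 0.4036 (SE 0.0739) and 0.3988 (SE 0.301), which did not exceed by more than an SE the bound of 0.40, set from the observed median before these fits were run. Of the 13 calls 10 and 7 were kept, with median fold changes of the 13 at 0.8945 and 0.8736 against 0.89 and median SEs at 0.114 and 0.152 against 0.101, but genes picked because they passed exclude nothing. A part played by striatal or meningeal tissue thus remains open for the whole list. Higher circulating corticosterone or an effect of the inhibitor on these genes remain open and untested.

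Haemoglobin transcripts were higher in both stressed groups than in NS. More red blood cells in the tissue may account for it: Hba-a1, Hba-a2, Hbb-bs, Hbb-b1 and Alas2 had about the same fold change in SA:ANH-vehicle, from 0.73 to 0.88 on the log2 scale, a range of 0.151 with a largest SE of 0.125 for a single gene. More vessel tissue is argued against as the full cause, because the endothelial list had a median of 0.07469 where the erythroid median was 0.77. The jackknife SE over genes, 0.0635, is a rough measure for a median and leaves out the spread between libraries. Endothelial scores were -0.0317, 0.0475 and -0.0407 in NS and 0.135, 0.0798 and -0.002 in SA:ANH-vehicle. Adjusted over the list alone 2 endothelial markers rose and 2 fell, so a smaller part played by vessel tissue stays open. Stress-driven formation of red cells, or less complete removal of blood, remain open and were not tested.

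Interferon response genes lay higher in SA:ANH-vehicle than in both other groups, and the 2 contrasts that show this share the SA:ANH-vehicle libraries. The list's score was 0.3526 higher there than in the other libraries, as large as in 1 of 84 splits of the 9 libraries, with 0.3141 as the highest other, which met a bound of under 5 of 84 that was wrong because the list had been picked from 29. Over all 29 lists, 7 of the 84 splits had a list as far from 0 as the interferon list's 2.44, in SDs over the splits. The highest other was 2.687. Those splits include the ones that set NS or SA:ANH-KDM5Ci apart, which may hold group differences rather than chance. The share of 7 of 84 thus cannot settle the question, and chance remains open. More microglia is argued against as the full cause of the fall to SA:ANH-KDM5Ci. There the microglia list had a median of 0.06367 (jackknife SE over genes, not libraries, 0.0465) against -0.52 for the interferon list. Its scores were 0.263, -0.101 and -0.0164 in SA:ANH-KDM5Ci and -0.00208, 0.0428 and 0.0218 in SA:ANH-vehicle. SA:ANH-KDM5Ci replicates 2 and 3 thus lay below all SA:ANH-vehicle libraries, and a smaller part played by microglia stays open. A part in the difference from NS, where the microglia list was called higher (median 0.09, camera adjusted p = 0.00334, and adjusted p = 0.594 with an estimated correlation), stays open, as does an antiviral tone raised by stress and lowered by the inhibitor. Between the stressed groups endothelial markers (median -0.16, 15 of 18 negative) and meningeal markers (median -0.67, 16 of 16 negative) were lower in SA:ANH-KDM5Ci as well. The 4 interferon calls were lost with the meningeal score as a covariate, though the fold changes of Irf9 and Isg15 did not shrink. A part played by vessel or meningeal tissue was not tested for the list and stays open.

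With 3 samples against 3 there are 10 splits, too few for a share under 0.05. In SA:ANH-vehicle against NS the real split called 2 genes and the highest other 7, with 2 of the 10 as large, and 13 lists against 15, with 3 as large. Between the stressed groups the values were 380 genes against 0, with 1 as large, and 10 lists against 11, with 4 as large, and for SA:ANH-KDM5Ci against NS 601 genes against 0, with 1 as large, and 13 lists against 13, with 2 as large. Of 100 splits of the 9 libraries into 3 groups, 72 gave a covariance as low as the real -0.0123, and the lowest other was -0.03275. These splits mix the SA:ANH-KDM5Ci libraries, which differed in 380 and 601 genes, into other groups. They therefore do not show what no effect would give, and whether chance gives -0.0123 stays open.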
